A study of Mus musculus with 6 samples.

How the data were processed

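Hnf4a ChIP-seq was carried out in iHep cells derived from fibroblasts of embryos at 13.5 days post coitum. Of the 6 samples, 3 were Hnf4a ChIP libraries and 3 were the matching inputs. Each ChIP sample had 1 deposited list of peaks, and no file of the inputs was used here. Groups were taken from the infection that the sample labels give. Per the labels, DNA was sheared by sonication and recovered with an antibody against Hnf4a.

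The submitters' processing notes name BWA 0.6.2, MACS2 2.1.0, bedtools 2.16.2 and the mouse genome build mm9, without saying what each was used for. The peak names carry the word MACS. Parameters, thresholds, and whether the input served as the background of the peak calls are not given in the sources used here. The lists have no header and give a chromosome, a start, an end, a name and a number for each peak. The last is the score that the authors deposited for each peak. Its scale is not stated, so it can be a log-scaled p-value, a log-scaled q-value or a fold enrichment. All scores exceed 5, with minima of 5.27, 5.31 and 5.24 in the Foxa1, Foxa2 and Foxa3 lists. Scores were therefore used to rank peaks within a list. They were compared between lists only to describe the lists and in 1 score-matched check. Peaks of equal score were ordered by chromosome and start. The Foxa1, Foxa2 and Foxa3 lists held 884, 838 and 339 distinct scores, so ranks and cuts by rank depend in part on that order, most in the Foxa3 list. Each list was called on 1 sample. The other deposited values are the starts and ends of the peaks, in bases. Starts in the lists count from 0 and are given here from 1. The peak ends reach 196814370 on chromosome 1, beyond the last gene of the GRCm38 gene table at hand, which ends at 195291439. That table therefore could not place peaks next to genes. The lists hold no counts of reads, so the depth of each library is unknown and no precision based on reads is given.

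The caller's smallest peak width differed between lists, at 270, 265 and 86 bases. The peak names of the Foxa1 and Foxa2 lists follow a common pattern that those of the Foxa3 list do not. A difference in processing or in the batch of cells between the Foxa3 list and the others cannot be told apart from the factor used, because each factor has 1 list. A narrow peak also has less chance to overlap another, and a list with closely spaced peaks counts 1 site more than once.

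Overlaps were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 and intervals with scipy 1.17.1. The overlap counts of peaks were identical to those of bedtools 2.31.1. A region is a set of peaks from any list that overlap by at least 1 base. The share for a pair of lists is the number of regions holding both, divided by the regions holding either. Intervals are Wilson intervals for shares, Newcombe intervals for differences of shares and, for the ratio between the pairs, percentiles of 1000 resamplings of 5 Mb windows. The ratios of the share of regions also held by the Foxa3 list have intervals from a normal approximation on the log scale, over regions. Each list was also placed at random on its own chromosomes 1000 times, up to the largest peak end seen on that chromosome, and moved as a whole by 20 to 500 kb 1000 times. Moved in this way, a mean of 2.90 Foxa1 peaks overlapped a Foxa2 peak. On simulated lists with 400 planted shared sites, the overlap rule returned 402 regions for Foxa1 with Foxa2, 401 for Foxa1 with Foxa3 and 402 for Foxa2 with Foxa3. Each planted site had the same width and nearly the same place in both lists, so this checks the counting only. It cannot show how many shared sites are missed where Foxa3 peaks are narrower.

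Choices made before the data were examined were the overlap rule, the alternatives to it and the regions to name. Named regions were the 10 highest peaks of each list, the 10 regions of all lists whose worst rank was best, and the 5 highest peaks of each list with no peak of another list within 1 kb. The text gives these in part. The densest windows, the segments of chromosome 6, the wide peaks and the chromosomes singled out were chosen after their values were seen. The range of scores from 10 to 20 was set after the quartiles by score had been seen and before its own values were. The alternatives fixed before the data were examined were a reciprocal overlap of 50%, centres within 500 bases, equal numbers of top peaks, the top 1000 peaks, the better-scoring 50%, autosomes only and quartiles by peak width. The planned annotation of peaks, the 10 gene lists and the 8 sequence motifs needed an mm9 annotation or genome and were not run. For that reason the introduced factors' own genes are not reported.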

Results

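The binding of Hnf4a across the genome was measured by ChIP-seq, in which DNA bound by a protein is recovered with an antibody and sequenced, in mouse hepatocyte-like cells. Hnf4a is a nuclear receptor that activates many liver genes, and Foxa1, Foxa2 and Foxa3 are related forkhead transcription factors of the liver lineage. The cells, called induced hepatocyte-like (iHep) cells, were made from C57BL/6 mouse embryonic fibroblasts by infection with Hnf4a together with Foxa1, Foxa2 or Foxa3. There were 3 Hnf4a ChIP libraries, 1 for each pair of factors, and 3 input libraries, for which no file was analysed here. The question of the design was which sites Hnf4a occupies in cells made with each of the Foxa factors.

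Each pair of factors was represented by 1 list of peaks, so no value below has a replicate error, and no test between conditions was possible. The intervals given for shares are 95% Wilson intervals. They cover counting error over peaks only, and peaks are not replicates of a condition. The lists held no read counts, so the depth behind each peak is unknown. Lists are named by the sample labels, as the Foxa1, Foxa2 and Foxa3 lists. The names of the peaks inside them carry the string F3 in the list labelled Foxa1, F2 in the list labelled Foxa2 and F1 in the list labelled Foxa3. What these strings stand for is not given in the sources used here, so which list belongs to Foxa1 and which to Foxa3 rests on the labels alone.

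The list labelled Foxa3 was the longest and its peaks were the narrowest and lowest in score. A difference in processing or batch between this list and the others cannot be told apart from the factor. This holds for every difference of the Foxa3 list given below. It held 2407 peaks, against 2002 in the list labelled Foxa1 and 1867 in the list labelled Foxa2. The median peak width was 120 bases in the Foxa3 list, 382.5 bases in the Foxa1 list and 364 bases in the Foxa2 list. The smallest width was 86, 270 and 265 bases in the same order, and 17.6% of the Foxa3 peaks had exactly that smallest width. The peaks covered 372 kb in the Foxa3 list, 821 kb in the Foxa1 list and 775 kb in the Foxa2 list. The score that the authors' peak caller gave each peak had a median of 9.20 in the Foxa3 list, 13.1 in the Foxa1 list and 13.1 in the Foxa2 list. In the Foxa3 list, 822 peaks (34.2%) had another peak of the same list with its centre within 500 bases, compared with 0 peaks in the Foxa1 list and 12 in the Foxa2 list. Joined at that distance, the Foxa3 list held 1951 sites, the Foxa1 list 2002 and the Foxa2 list 1861.

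A common set of 451 regions carried an Hnf4a peak in all 3 lists. These were 10.2% of the 4419 regions that any list held. The lists labelled Foxa1 and Foxa2 had 420 further regions in common that the Foxa3 list lacked. The Foxa2 and Foxa3 lists alone shared 183 regions, and the Foxa1 and Foxa3 lists alone shared 159. Regions of a single list were the most frequent, with 1424 in the Foxa3 list, 970 in the Foxa1 list and 812 in the Foxa2 list. They made up 64.2% (62.2 to 66.2) of the Foxa3 regions, 48.5% (46.3 to 50.7) of the Foxa1 regions and 43.5% (41.3 to 45.8) of the Foxa2 regions. Closely spaced Foxa3 peaks stayed separate regions unless a peak of another list joined them, which can raise the Foxa3 count and share. The Foxa3 list held 2217 regions but 1951 sites joined within 500 bases, and these shares were not computed by joined sites.

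**Figure D1:**
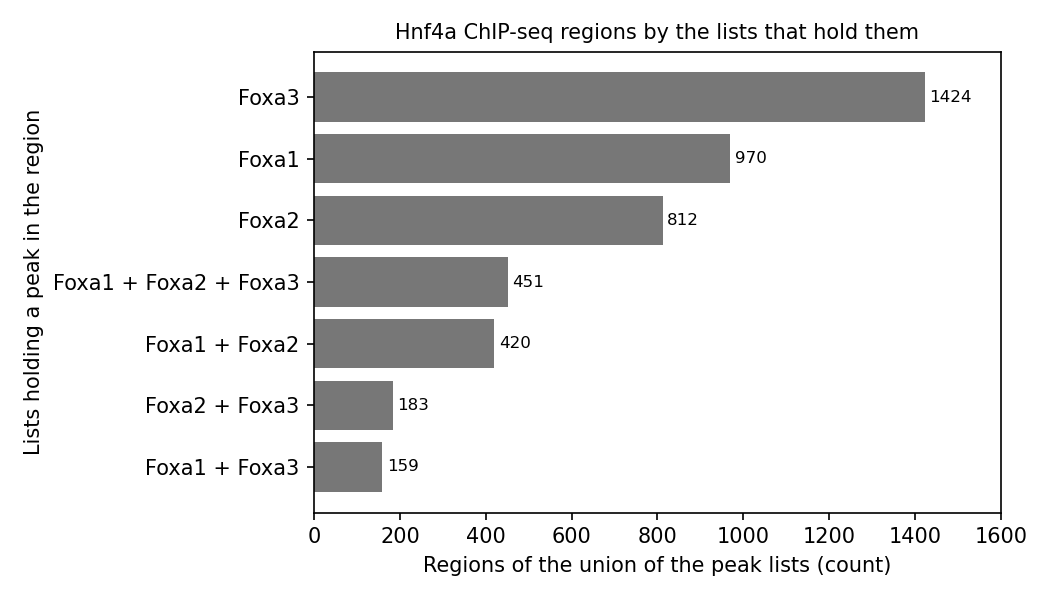
Number of regions (horizontal axis, count) by the combination of lists that hold a peak in the region (vertical axis), where peaks overlapping by at least 1 base form a region. The 451 regions of all lists are fewer than the regions of each single list, which number 1424, 970 and 812.

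The lists labelled Foxa1 and Foxa2 shared more of their regions with each other than either did with the Foxa3 list. By another measure, the share of peaks with a score from 10 to 20 that overlapped another list, the intervals of the differences held 0. Of the regions held by the Foxa1 or the Foxa2 list, 29.1% (27.5 to 30.7) were held by both. The value was 16.4% (15.3 to 17.7) for Foxa1 with Foxa3 and 17.7% (16.5 to 19.0) for Foxa2 with Foxa3. The first share was 1.70 times the mean of the other pairs, with a 95% interval of 1.58 to 1.84 from 1000 resamplings of 5 Mb windows. By peak, 43.6% of the Foxa1 peaks overlapped a Foxa2 peak and 30.1% overlapped a Foxa3 peak. Of the Foxa2 peaks, 46.7% overlapped a Foxa1 peak and 33.4% a Foxa3 peak. Of the Foxa3 peaks, 30.8% overlapped a Foxa1 peak and 31.7% a Foxa2 peak. When peaks were placed at random on their own chromosomes 1000 times, a mean of 1.24 of the 2002 Foxa1 peaks overlapped a Foxa2 peak, compared with the 873 observed, and the highest of the placements gave 7. Among peaks with a caller score from 10 to 20, a choice made after seeing the data, 44.4% of the Foxa2 peaks and 41.4% of the Foxa3 peaks overlapped a Foxa1 peak, a difference of 3.02 points (-1.46 to 7.46, Newcombe interval). At the same scores 41.5% of the Foxa1 peaks and 41.4% of the Foxa3 peaks overlapped a Foxa2 peak, a difference of 0.109 points (-4.29 to 4.49). Counted by sites joined within 500 bases, with a best score in the same range, the differences were 1.55 points (-3.10 to 6.18) and -1.84 points (-6.42 to 2.72). This range held 1050 of the 1867 Foxa2 peaks but 851 of the 2407 Foxa3 peaks, and the scale of the score may differ between lists. It lies above the Foxa3 median of 9.20 but spans the middle of the Foxa2 list, with quartiles of 10.1 and 18.3. If the scales differ, higher-ranked Foxa3 peaks are compared with middling Foxa2 peaks, which can make the differences smaller. Matched by rank instead, the ratio between the pairs was 1.74 with equal numbers of top peaks and 1.58 with the top 1000 peaks. With peak centres within 500 bases in place of overlap, which depends less on width, the ratio between the pairs was 1.53. A rule of 50% overlap of both peaks gave 6.28, but a Foxa3 peak of median width cannot cover 50% of a Foxa1 or Foxa2 peak of median width.

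Sharing followed the strength of the peaks within each list. In the quartile of the Foxa1 list with the highest scores, 65.9% (61.6 to 69.9) of the peaks overlapped a Foxa2 peak, and in the quartile with the lowest scores 29.6% (25.8 to 33.7) did. For Foxa2 peaks overlapping a Foxa1 peak, the values were 72.2% (67.9 to 76.0) in the highest and 26.8% (23.0 to 31.0) in the lowest quartile. Foxa3 peaks overlapped a Foxa1 peak in 47.8% (43.9 to 51.8) of the highest and 21.3% (18.2 to 24.7) of the lowest quartile. Foxa1 peaks overlapped a Foxa3 peak in 49.5% (45.1 to 53.9) of the highest and 19.0% (15.8 to 22.7) of the lowest quartile. The highest and lowest quartiles also differed by more than their intervals for Foxa2 peaks in the Foxa3 list, at 54.4% and 16.5%, and for Foxa3 peaks in the Foxa2 list, at 46.3% and 21.8%. The quartiles are not matched in score between lists, since the highest quartile began at 18.2 in the Foxa1 list, 18.3 in the Foxa2 list and 10.8 in the Foxa3 list.

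**Figure D2:**
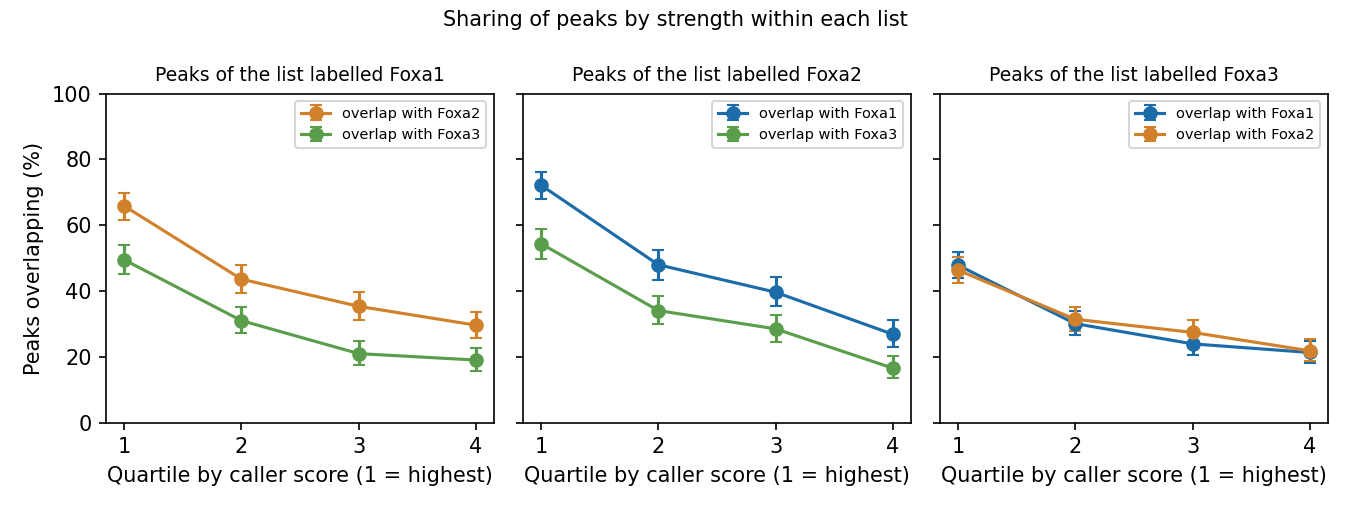
Share of the peaks of each list (percent, vertical axis) that overlap a peak of another list, by quartile of the list's own caller score (horizontal axis, 1 is the highest); colours mark the other list and bars are 95% Wilson intervals. In each panel the share falls from the first quartile to the fourth, for example from 65.9% to 29.6% for Foxa1 peaks in the Foxa2 list.

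The same site ranked first in each list. It lay on chromosome 5 at 9040593 to 9041407 (mm9, as for all positions given here), with caller scores of 136.9, 107.3 and 42.9 in the Foxa1, Foxa2 and Foxa3 lists. The region on chromosome 4 at 141115490 to 141116335 ranked 2, 4 and 4 in the same order. A region on chromosome 6 at 85087084 to 85087831 ranked 5, 8 and 2. The region on chromosome 16 at 52333617 to 52334190 ranked 21, 6 and 36. The other regions among the 10 with the best rank across all lists lay on chromosome 1 at 161180428 to 161181031, on chromosome 2 at 38341163 to 38341903, on chromosome 3 at 97648366 to 97649111 and 116414968 to 116415606, on chromosome 4 at 141285039 to 141285712 and on chromosome 6 at 143100674 to 143101296. Which genes lie at these positions was not analysed here, because the gene table at hand is for another genome build.

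All 10 of the strongest Foxa1 peaks overlapped a peak of both other lists. Among them were the peaks on chromosome 11 at 115738347 to 115739064, on chromosome 13 at 75361169 to 75361855, on chromosome 14 at 70457216 to 70457943 and on chromosome 18 at 43891650 to 43892253. For some of them the ranks lay far apart. The peak on chromosome 18 ranked 7 in the Foxa1 list, 1695 in the Foxa2 list and 953 in the Foxa3 list. A peak on chromosome 6 at 85105032 to 85105693 ranked 4 in the Foxa1 list and 3 in the Foxa2 list but 2252 in the Foxa3 list. Of the 10 strongest Foxa3 peaks, 8 overlapped both other lists, including those on chromosome 8 at 13200587 to 13201240 and at 125575290 to 125575694. The Foxa3 peak on chromosome 6 at 8703033 to 8703405 ranked 3 there, 439 in the Foxa1 list and 434 in the Foxa2 list. Of the 10 strongest Foxa2 peaks, 6 overlapped both other lists and 4 overlapped neither. These 4 lay on chromosome 2 at 98502271 to 98503254 and 98506254 to 98507608, and on chromosome 9 at 3005604 to 3008932 and 3009115 to 3038420. The last of them was 29306 bases wide, compared with a median of 364 bases in the Foxa2 list. Whether these 4 peaks mark binding of Hnf4a was not tested, so they cannot be read as sites particular to Foxa2.

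Some strong peaks were found in 1 list only, with no peak of another list within 1 kb. In the Foxa1 list the highest of these lay on chromosome 12 at 92934676 to 92935245 with rank 14, on chromosome 2 at 133575824 to 133576399 with rank 15 and on chromosome 11 at 83830559 to 83831066 with rank 20. In the Foxa3 list they lay on chromosome 16 at 57391625 to 57391718 with rank 9, on chromosome 11 at 94019694 to 94020248 with rank 40 and on chromosome 1 at 37947296 to 37947388 with rank 44. Those on chromosomes 16 and 1 were 94 and 93 bases wide, near the smallest width of 86 bases in that list. In the Foxa2 list the highest 5 were all in 2 places. These were 3 peaks covering 38.2 kb of chromosome 9 between 2999903 and 3038420, of which 1 was 29306 bases wide, and a pair on chromosome 2 at 98502271 to 98503254 and 98506254 to 98507608. The median width in the Foxa2 list was 364 bases. Whether these 5 peaks mark binding of Hnf4a was not tested, so they cannot be read as sites particular to Foxa2. Leaving out the 4 peaks wider than 2000 bases and their neighbours within 100 kb left the ratio between the pairs at 1.70. The wide peaks were those 3 on chromosome 9 and another on chromosome 10, so the pair on chromosome 2 stayed in. Few peaks were left out, so the ratio could hardly move.

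Chromosome 6 carried more of the Foxa3 list than of the other lists. It held 305 of the Foxa3 peaks, 12.7% (11.4 to 14.1), compared with 7.34% (6.28 to 8.57) of the Foxa1 peaks and 7.61% (6.49 to 8.90) of the Foxa2 peaks. The Foxa3 share was 1.70 times the mean of the other lists. Along the chromosome the excess differed between segments, which were set after the counts had been seen. In its first 30 Mb the lists held 15, 17 and 17 peaks in the order Foxa1, Foxa2 and Foxa3. From 30 to 150 Mb, without the bin from 40 to 50 Mb, they held 92, 81 and 266 peaks. The Foxa3 list gave 34.7% (22.9 to 48.7) of the peaks of all lists in the first 30 Mb and 37.0% (35.7 to 38.3) on the other chromosomes. From 30 to 150 Mb without the bin from 40 to 50 Mb it gave 60.6% (55.9 to 65.1). The lists held 40, 44 and 22 peaks in that bin, so leaving it out raises the Foxa3 share by construction. Chromosome 11 held 8.31% (7.27 to 9.48) of the Foxa3 peaks, 6.19% (5.22 to 7.34) of the Foxa1 peaks and 5.36% (4.42 to 6.47) of the Foxa2 peaks. The Foxa3 list had the lowest share on the X chromosome, with 8 peaks or 0.332% (0.169 to 0.655), compared with 24 peaks or 1.199% (0.807 to 1.78) in the Foxa1 list and 36 peaks or 1.93% (1.40 to 2.66) in the Foxa2 list.

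**Figure D3:**
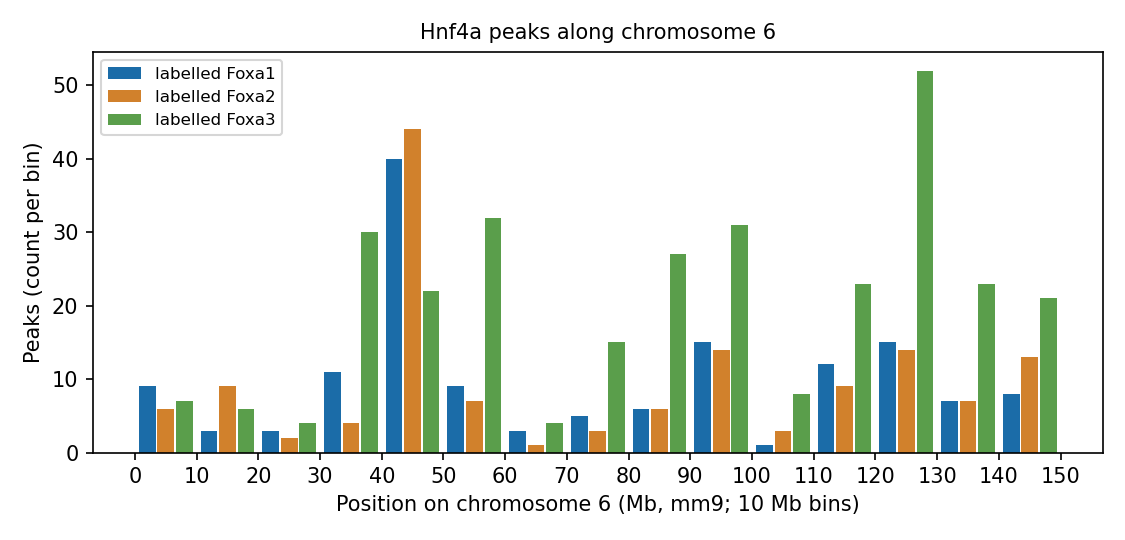
Number of peaks (vertical axis, count) in 10 Mb bins along chromosome 6 (horizontal axis, Mb, mm9) for the lists labelled Foxa1, Foxa2 and Foxa3. The lists are alike up to 30 Mb, with 15, 17 and 17 peaks, and the Foxa3 bars are the highest from there on except in the bin from 40 to 50 Mb, where the Foxa1 and Foxa2 lists have 40 and 44 peaks and the Foxa3 list 22.

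The densest stretch of the Foxa1 and Foxa2 lists was a block of 121 kb on chromosome 6 at 47601609 to 47723082, found by joining the Foxa1 and Foxa2 peaks of the window from 45 to 50 Mb across gaps of up to 60 kb. It held 33 Foxa1 peaks and 39 Foxa2 peaks but 5 Foxa3 peaks. In this block 26 of the Foxa1 peaks overlapped a Foxa2 peak. The 15 Foxa2 peaks with a score of at least 18 followed each other at a median distance of 4381 bases between starts, and 10 of their 14 distances lay between 4000 and 4600 bases. This cut was not among the choices made before the data were examined. With the lower-scoring Foxa2 peaks of the block included, neighbouring starts lay closer together, so the spacing is that of the subset only. Without the window from 45 to 50 Mb, chromosome 6 held 5.65% of the Foxa1 peaks, 5.53% of the Foxa2 peaks and 12.2% of the Foxa3 peaks.

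**Figure D4:**
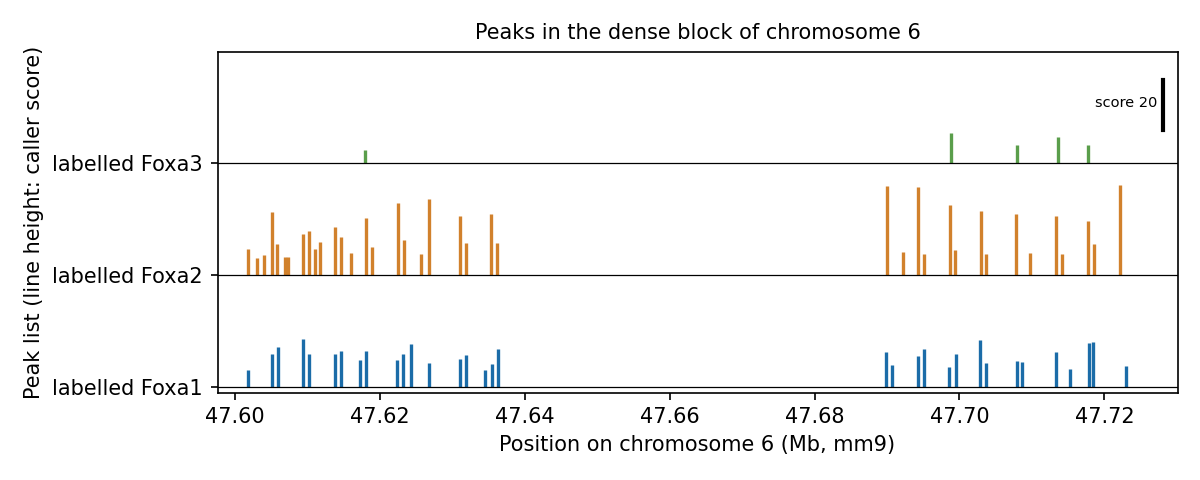
Peaks of each list at 47601609 to 47723082 of chromosome 6 (horizontal axis, Mb, mm9); each vertical line is a peak at its centre, and its height is the authors' caller score on the scale of the black bar. The 39 Foxa2 and 33 Foxa1 peaks form 2 groups, and the Foxa3 list has 5 peaks there.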

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

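Each list stands alone, so no replicate could be left out and no spread between replicates is known. No paired analysis was possible because each group has 1 list. The planned results on annotation, gene lists and motifs, with their alternatives, were not run for want of mm9 sequence and genes. The removal of chromosome 6, of the window from 45 to 50 Mb, of wide peaks, the removal of the densest Foxa3 window of chromosome 6, random placement within the dense block, the range of scores from 10 to 20 by peak and by site, and the joining of peaks within 500 bases were chosen after seeing the data. For the range of scores, differences between shares were taken and no ratio. The ratio of the Foxa1 and Foxa2 share to the other pairs stayed above 1 under every alternative for which it was computed, between 1.53 and 6.28, and the Foxa3 list kept the highest share of regions of its own. No alternative for the ratio or for that share joined closely spaced Foxa3 peaks, which can raise both. Autosomes only, the removal of chromosome 6, and the removal of wide peaks moved none of these overlap results beyond their intervals. With a reciprocal overlap of 50%, 158 regions were in all lists, the shares of the pairs Foxa1 with Foxa2, Foxa1 with Foxa3 and Foxa2 with Foxa3 were 25.9%, 3.96% and 4.27%, the ratio was 6.28, and the regions in no other list were 58.5%, 55.3% and 90.3% in the order Foxa1, Foxa2 and Foxa3. This rule is hard to meet for peaks of unequal width by its construction. With centres within 500 bases, the pairs with Foxa3 rose to 18.1% and 20.1%, the ratio was 1.53 and 59.6% of Foxa3 regions were in no other list. With equal numbers of top peaks, 46.3% of Foxa2 and 61.2% of Foxa3 regions were in no other list. With the top 1000 peaks, fewer by construction, 179 regions were in all lists, the pairs shared 24.5%, 14.8% and 16.2%, the ratio was 1.58, and 52.9% of Foxa1 and 50.6% of Foxa2 regions were in no other list. With the better-scoring 50%, 190 regions were in all lists, the pairs shared 24.5%, 15.1% and 15.9%, the ratio was 1.58, 52.6%, 48.3% and 66.2% of regions were in no other list, and chromosome 6 held 11.4% of the Foxa3 peaks. With quartiles by width, the strongest quartile of Foxa2 in Foxa1 was 67.0%, that of Foxa3 in Foxa1 51.2% and that of Foxa3 in Foxa2 54.7%, and the weakest quartile of Foxa3 was 15.97% in Foxa1 and 18.5% in Foxa2. The cause was not tested except where stated. Without the window from 45 to 50 Mb, chromosome 6 held 5.65% of Foxa1 and 5.53% of Foxa2 peaks. Of the 10 named regions of all lists, 7 still met a reciprocal overlap of 50%.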

Other observations

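Regions bound in all lists were sometimes close together. Of the 451, 38 lay in 16 groups in which each region lay at most 25 kb from the next. The largest group, of 4 regions on chromosome 6 at 47698312 to 47717974, lay in the dense block at 47601609 to 47723082, and without the block 34 regions were in 15 groups. The groups of 3 regions were on chromosome 15 at 36828363 to 36863597, 3197548 to 3221123 and 75674604 to 75710167, and on chromosome 8 at 129348504 to 129354023. The groups whose best region ranked highest across the lists were pairs, on chromosome 4 at 141115490 to 141127977 and on chromosome 6 at 85087084 to 85105693, and the rank of the other region of each pair was not counted. Across the regions that 2 lists shared, the scores of the lists followed each other weakly by rank, with a Spearman correlation across regions of 0.27 for Foxa1 with Foxa2, 0.18 for Foxa1 with Foxa3 and 0.23 for Foxa2 with Foxa3. The Pearson correlations were higher, at 0.47, 0.37 and 0.34 in the same order. They were taken on unscaled scores, whose highest value lay at the same site in each list, and were not computed without it. Regions are not independent replicates. Regions of all lists had median ranks at 27.6%, 26.1% and 28.8% of the Foxa1, Foxa2 and Foxa3 lists, compared with 60.1%, 64.4% and 57.1% for regions of a single list.

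The tests of a tandem array, of random placement within the block, of a single local cluster, and of chromosome 6 outside 45 to 50 Mb were chosen only after the result was seen. The others were set before their results were seen, though after the pattern they address. The test at scores from 10 to 20 was added once the quartiles by score had been seen.

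The block at 47601609 to 47723082 of chromosome 6 holds many Foxa1 and Foxa2 peaks. In the window from 45 to 50 Mb, 77.8% (61.9 to 88.3) of the Foxa1 peaks overlapped a Foxa2 peak, compared with 43.0% elsewhere, but peaks so dense also meet by chance, so this share alone decides nothing. With the peaks of both lists placed at random within their groups of the block 1000 times, a median of 16 of the 33 Foxa1 peaks (48.5%) overlapped a Foxa2 peak and the highest number was 24, compared with the 26 observed. Calls placed independently in each list within the groups therefore do not account for the overlap, while a background with the same fine shape in both lists was not tested. A tandem array of one repeated sequence is a candidate explanation that was not decided, since the spacing of the higher-scoring Foxa2 peaks prompted it and the sequence was not analysed here. Over all Foxa2 peaks of the block, the fullest 200-base bin of distances between Foxa2 peak starts, 4200 to 4400 bases, held 17 pairs, compared with a median of 9 and a highest value of 15 in 1000 random placements within the 2 groups of peaks. The Foxa1 list had the same fullest bin, with 15 pairs, compared with a median of 7 and a highest value of 14. Since 26 of its 33 peaks overlapped a Foxa2 peak, it is not a separate test. In the Foxa3 list, with 5 peaks, the fullest bin held 1 pair, as did the median placement. Whether Hnf4a occupied each unit, or reads from 1 unit were spread over copies of it, stays open without the reads, as does the low number in the Foxa3 list.

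The excess of Foxa3 peaks on chromosome 6 was not one local cluster, since the share was still 1.54 times the mean of the other lists without its densest 5 Mb window, which was taken out of the Foxa3 list alone, and 1.63 times with the same window taken out of all lists. Extra copies of the chromosome, or of its part beyond 30 Mb, may raise the power to call peaks there. This stays open. Regions held by both other lists were also called in the Foxa3 list 1.08 times (0.880 to 1.33, normal approximation on the log scale) as often on chromosome 6 as elsewhere, an interval that holds both no difference and a clear one. Outside 45 to 50 Mb the ratio was 1.40 (1.16 to 1.67), but that window was chosen for its Foxa1 and Foxa2 peaks and only 7 of its 28 regions were in the Foxa3 list, so leaving it out raises the ratio by construction. More Hnf4a sites on chromosome 6 with this Foxa factor were not tested. Input coverage was not analysed here.

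The lower sharing of the Foxa3 list was tested against 3 technical explanations. Closely spaced Foxa3 peaks were not joined when the ratios between the pairs were computed, which can raise these ratios. Narrower peaks are not the whole of it, since the ratio between the pairs was 1.53 (1.42 to 1.64, resampled windows) with centres within 500 bases, and neither is the excess on chromosome 6, with a ratio of 1.65 (1.53 to 1.77) without that chromosome. Weaker peaks remain a candidate explanation: the strongest quartile of Foxa2 exceeded that of Foxa3 by 24.3 points (18.5 to 29.9, Newcombe interval) in overlap with Foxa1, but these quartiles begin at scores of 18.3 and 10.8, so the test does not match strength. By width in place of score the difference was 15.9 points (9.94 to 21.6), from 67.0% and 51.2%. By the rule written before the value by score was seen, the 24.3 points count against weaker peaks as the only cause, and the rule was set aside only after the value was known. At scores from 10 to 20 the difference was 3.02 points (-1.46 to 7.46). At the same scores, Foxa1 exceeded Foxa3 by 0.109 points (-4.29 to 4.49) in overlap with Foxa2. By sites joined within 500 bases these differences were 1.55 points (-3.10 to 6.18) and -1.84 points (-6.42 to 2.72), so the second changed sign and all these intervals hold 0, although the scale of the score may not be alike in lists processed separately. The range also lies above the Foxa3 median but spans the middle of the other lists, which can make the differences smaller if the scales differ. A difference in Hnf4a binding between cells made with Foxa3 and with the other factors was not tested apart from these, and a batch of cells or libraries cannot be told apart from the factor with 1 list each.

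The wide Foxa2 peaks at the start of chromosome 9 and the peaks of chromosome 2 at 98502271 to 98507608 had scores up to 77.8 and 85.0, and no peak of the other lists was given in either place. Whether these peaks mark binding of Hnf4a was not tested.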
